A study of Mus musculus with 3 samples.

How the data were processed

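Polyadenylated RNA from primary mouse macrophages grown out of bone marrow was sequenced in 3 libraries, labelled biological replicates 1, 2 and 3 of a single group. Per the labels, the cells came from the inbred strain C57BL/6J and were exposed to 100 ng/mL of the stimulus for 180 min, and each library was prepared from 1 µg of RNA with a stated size range of 250 to 400, whose unit the labels leave out. The labels disagree on the stimulus. The description names lipid A, the membrane-anchored part of bacterial lipopolysaccharide that Toll-like receptor 4 (TLR4) binds, whereas the source name and the treatment field name lipoprotein A and call it a protein. The text below says lipid A, after the description, and no value here depends on the name. All 3 libraries carry the same donor identifier, so the labels tie the replicates to separate biological replicate numbers but not to separately identified animals, and the spread between them was not split into biological and technical parts.

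No control or unstimulated group was analysed here. No value below is therefore a response to the stimulus: levels are compared between genes within these libraries, and replicates are compared with each other. The labels do not state the question of the study.

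For every library the authors deposited a gene quantification and a transcript quantification derived from an alignment to the transcriptome, and a second transcript quantification derived directly from the reads and an index, per the text files deposited beside them, which also name the mm10 assembly and the GENCODE M21 annotation. The aligner, the quantifiers and their versions are not given in the sources used here. Per the file headers, the deposited gene quantification holds expected counts (estimated fragment counts, which need not be whole), TPM (length-scaled shares of all transcripts) and FPKM (the same scaled by transcript length and library total, in fragments). The deposited transcript quantification holds these and the percent of each gene's abundance that a transcript makes up, and the second quantification holds estimated counts and TPM, per the file headers. Replicates were not pooled by the authors. Whether the libraries kept strand is not given in the sources used here, so genes that overlap on opposite strands were not told apart.

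Both TPM and FPKM were used as deposited. TPM was the main unit for levels, FPKM served only for an alternative count of detected genes, and the deposited percent column was recomputed from transcript TPM as the share of each gene's summed TPM. The second quantification was summed over the transcripts of each gene. All 55536 mouse gene IDs of the gene quantification were found in GENCODE M21, which gave symbols, types and positions (mm10, counted from 1). Where a symbol belonged to more than 1 gene ID, the ID with the highest mean TPM was used; this applied to 2 symbols of the lists and pairs.

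The deposited expected counts of the gene quantification summed to 24478989, 34675476 and 60645458 in replicates 1, 2 and 3, and those of the second quantification to 32095496, 38175617 and 67511023. A further 26248 entries with a numeric identifier held 1, 0 and 0 counts. Entries of the phiX control sequence held 0.117%, 0.0993% and 0.082% of the counts, and entries of ERCC spike-in sequences held 0. These entries stayed out of the library sizes and tests on counts, while deposited TPM is scaled over all entries, of which phiX took 348, 290 and 246 TPM. A count of 0 allows a share of up to 3 counts of the total, which is 1.23e-05%, 8.66e-06% and 4.95e-06% of the counts in replicates 1, 2 and 3. Such limits and the intervals below cover counting error only, since amplified fragments without molecular identifiers are not independent molecules.

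A gene was called detected at 1 TPM or more in all 3 replicates. For each of 35 gene lists, the level was the median over members of log2(TPM + 0.1) minus the median over detected genes, computed in each replicate, with mean and SD over the 3 replicates. Differences on this scale understate ratios of genes with low TPM. An exact two-sided sign-flip permutation test over replicates was run; with 3 replicates it cannot go below p = 0.25, so it cannot pass a threshold of 0.05 in this design. The list median was also ranked among 10000 random lists of the same size drawn from detected genes. For 30 gene pairs, log2((TPM + 0.1)/(TPM + 0.1)) was computed in each replicate, with the same test, and the mean was set against its SD. Of the lists, 22 cover functions, controls and RNA classes, and 13 hold markers of other cell types. The lists and pairs, the tests of this report and the alternative settings named below as chosen in advance were fixed before the data were examined; the tests of explanations in the closing observations were not.

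Spread between replicates was measured on expected counts rounded to whole numbers, with edgeR 4.0.16 in R 4.3.3: low genes were removed with its default filter (11611 genes stayed), libraries were scaled with TMM factors (0.988, 1.054 and 0.96), and a common and a gene-wise biological coefficient of variation were fitted with an intercept only. A chi-square test of equal rates over the 3 libraries, with Benjamini-Hochberg adjustment over the genes tested, compared each gene with counting noise; it is a test on these libraries and not on conditions. In each replicate, the deviation of a gene was its log2 CPM (TMM-scaled, prior count 2) minus the mean of the other replicates. The median deviation of each list with at least 3 tested members was ranked among 10000 random lists matched on mean expression in 20 bins. As this sets 1 library against the others, it has no p-value, and the 3 deviations of a gene sum to 0, so a high value in a replicate lowers the others. Random lists lack the shared regulation of a real list, which makes extreme ranks more frequent. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1; figures were drawn with matplotlib 3.10.9.

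The procedures were tested on simulated counts made from the real gene means and library sizes, over 11611 genes. With counting noise only, the chi-square test called 0 genes. With 200 genes changed in a single library, it called 79.1% of those changed by 1.5-fold, 91% at 2-fold and 100% at 4-fold, with 8 unchanged genes called. Coefficients of variation of 0.1, 0.2 and 0.3 were recovered as 0.1, 0.2 and 0.297. Lists shifted by 0.58, 1 and 2 (log2) in replicate 2 were recovered at 0.58, 1.03 and 2.02, and 4% of 200 unchanged lists fell outside the central 95% of random lists. The unchanged lists were random genes with independent spread, so this rate does not carry over to lists of co-regulated genes.

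Genes named in the text follow a rule set in advance: the 3 members with the highest and the 1 with the lowest mean TPM in each functional or control list, the 2 highest members of each list of another cell type, both genes of each pair, the 10 most abundant nuclear protein-coding genes, and the 10 genes with the largest gene-wise coefficient of variation among those with a mean of 10 TPM or more. This gave 165 genes. Others are named as chosen after their values were seen, or as nuclear copies found by the sequence search described below. Some results that need withheld genes are not reported here. Alternative settings chosen in advance were other thresholds, pseudocounts, reference genes, filters and scalings (DESeq2 1.42.0 size factors, library totals), the second quantification, counts without length scaling, deposited TPM and unmatched random lists for the deviations, and leaving out each replicate in turn. Leaving out replicates from the list deviations and the Nos2/Arg1 count ratio, and removing spline trends on log2 length and GC content from the deviations, were added after seeing the data. Copies of mitochondrial genes were searched among GENCODE M21 transcripts with blastn 2.17.0, at 99% identity or more over at least 200 nt.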

Results

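Bone-marrow-derived macrophages, phagocytes grown from mouse marrow, were profiled by polyadenylated RNA sequencing 180 min after exposure to 100 ng/mL lipid A, in 3 biological replicates of a single group. The libraries held 24450338, 34641026 and 60595742 expected counts of mouse genes in replicates 1, 2 and 3. In all 3 replicates together, 10026 genes reached 1 TPM, of which 9388 are protein-coding, 177 are annotated as lincRNA or antisense and 309 as pseudogenes. Single replicates reached 10744, 10860 and 10489 genes. At the upper end, 1142 genes stood at 100 TPM or more in every replicate. The median detected gene lay at 14.6 ± 0.535 TPM (SD, n = 3), and list levels below are given relative to it on the log2 scale.

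The most abundant nuclear protein-coding gene was Fth1, the ferritin heavy chain gene (chromosome 19, 9980598 to 9985098, mm10), at 24122 ± 5416 TPM (SD, n = 3), followed by Lyz2, the lysozyme gene (chromosome 10, 117277331 to 117282321), at 18063 ± 4872 TPM. Ftl1, Psap, Ctsb, Apoe, Ctsd, B2m and Gpnmb also belonged to the 10 highest, with 17110, 12118, 10944, 10400, 9331, 9353 and 8929 TPM. The remaining member of the 10 was Cxcl10, a chemokine gene induced by interferon (chromosome 5, 92346638 to 92348889), at 10183 ± 1550 TPM. Macrophage identity genes as a list had a median of 736 ± 69.6 TPM, 5.63 ± 0.18 (log2) above the median detected gene, and 29 of 30 were detected. The exception was Cx3cr1, a fractalkine receptor gene, at 0.02, 0.15 and 0.04 TPM in replicates 1, 2 and 3. Reads of Lyz2, H2-K1, H2-D1 and other members of gene families can be shared with near-identical relatives, and their single values are uncertain to that extent.

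Interferon-stimulated genes formed the highest functional list after macrophage identity. All 32 members were detected and 28 stood at 100 TPM or more in every replicate. Their median was 569 ± 35.6 TPM, 5.26 ± 0.10 (log2) above the median detected gene. Besides Cxcl10, the chemokine gene Ccl5 reached 6482 ± 1075 TPM and Rsad2, which encodes the antiviral protein viperin (chromosome 12, 26442746 to 26456452), 5919 ± 624 TPM. The lowest member was Cxcl11, at 74.3 ± 23.4 TPM, which is annotated as a polymorphic pseudogene. Within pairs, Cxcl10 exceeded Cxcl9 by 6.05 ± 0.28 (log2; 66.4-fold) and Irf7 exceeded Irf3, a related transcription factor gene, by 4.64 ± 0.12 (24.9-fold). Ifit1 lay above Ifit3, with a log2 Ifit3/Ifit1 ratio of -0.51 ± 0.13. The receptor genes Ifnar2 and Ifnar1 of type I interferon stood at 189 ± 7.71 and 120 ± 8.83 TPM. The list that also holds the interferon genes had a median level of -2.64 ± 1.48 with 5 of 10 members detected, 2.67 when only detected members were kept, -1.94 without replicate 1 and -3.40 without replicate 2. Ifna1 had 0 counts in every replicate. Ifnb1, chosen after its values were seen, had 9.34, 29.6 and 8.98 TPM in replicates 1, 2 and 3.

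Inflammatory cytokine and mediator genes were high as a list. Their median was 90.8 ± 35.9 TPM, 2.54 ± 0.60 (log2) above the median detected gene, and 23 of 27 were detected. The chemokine genes Ccl4 and Ccl3 led with 4428 ± 1331 and 2795 ± 1394 TPM, and Tnf (chromosome 17, 35199381 to 35202007) followed with 1522 ± 392 TPM. Csf3, a granulocyte growth factor gene, was lowest at 0, 0.23 and 0.09 TPM in replicates 1, 2 and 3. Tnf exceeded Il10, an anti-inflammatory cytokine gene, by 5.16 ± 0.36 (log2; 35.8-fold), and Il6 lay below Tnf with a log2 ratio of -3.61 ± 0.32. Il12b, whose product is shared by interleukin 12 and interleukin 23, stood at 302 ± 98.1 TPM against 2.25, 6.07 and 1.10 TPM of its partner Il12a, a log2 ratio of 6.81 ± 1.09, which was 6.19 without replicate 3. The ratio of Il12b to Il23a was 7.83 ± 2.34, and 7.14, 9.18 and 7.18 without replicates 1, 2 and 3. In replicate 2 Il23a reached 11.1 TPM, against 0.23 and 0.46 TPM in replicates 1 and 3. Ccl5 exceeded Ccl2 by 2.48 ± 1.17, and by 3.15 without replicate 2. Ptgs2, the inducible cyclooxygenase gene, exceeded its constitutive relative Ptgs1 by 3.05 ± 0.87. Il1b and Il1a, the interleukin 1 genes, differed by 0.42 ± 0.38 with 2 of 3 replicates on the same side, and this ratio turned to -0.24 in counts without length scaling. Il1rn, which encodes the interleukin 1 receptor antagonist, did not differ from Il1b beyond the spread between replicates (0.04 ± 1.12; -0.16, 0.67 and -0.40 without replicates 1, 2 and 3). Nos2, the inducible nitric oxide synthase gene, had 120 ± 6.40 TPM and 37367 expected counts over the 3 libraries, against 2 counts of Arg1, the arginase gene; the ratio of counts was 18684, with an exact 95% interval for counting error of 5172 to 154281. Both Arg1 counts lay in replicate 2, so without it no ratio could be formed, and the ratio was 8922 without replicate 3 (2469 to 73673) and 14916 without replicate 1 (4129 to 123168). These ratios of counts are not scaled for length. As a pair, the log2 Nos2/Arg1 ratio of TPM plus 0.1 was 9.97 ± 0.51. It was 6.88 with a pseudocount of 1 TPM, 9.36 in the second quantification and 13.7 in counts without length scaling.

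Feedback regulators of the pathway were all detected (22 of 22), with a median of 199 ± 25.2 TPM and a level of 3.75 ± 0.16. Nfkbia, an inhibitor of NF-kB, stood at 981 ± 170 TPM, Il1rn at 980 ± 73.5 TPM and Tnip3 at 962 ± 387 TPM, while Irak3 was lowest at 14.9 ± 2.56 TPM. Nfkbia exceeded Nfkbib by 2.06 ± 0.26 (log2) and Nfkbie by 2.23 ± 0.30. Tnfaip3 exceeded Cyld, another deubiquitinase gene, by 5.14 ± 0.06 (35.4-fold), and Socs3 exceeded Socs1 by 3.06 ± 0.47. The NF-kB subunit genes had a level of 3.35 ± 0.30, led by Nfkb2 at 360 ± 21 TPM. Nfkb1 lay above Rela by 0.86 ± 0.21, and Nfkb2 above Relb by 2.14 ± 0.19. Rel lay below Rela with a log2 ratio of -1.52 ± 0.36, which turned to 0.21 in counts without length scaling. Genes of the TLR4 signalling pathway stood close to the median detected gene (0.70 ± 0.12; 20 of 20 detected), led by the co-receptor gene Cd14 at 1652 ± 328 TPM. Of 12 Toll-like receptor genes, 9 were detected, at a level of 1.73 ± 0.13. Tlr2 reached 581 ± 69.3 TPM and exceeded Tlr4, at 21.4 ± 2.71 TPM, by 4.76 ± 0.29 (27-fold), and Tlr12 was lowest at 0.06, 0 and 0.03 TPM.

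**Figure D1:**
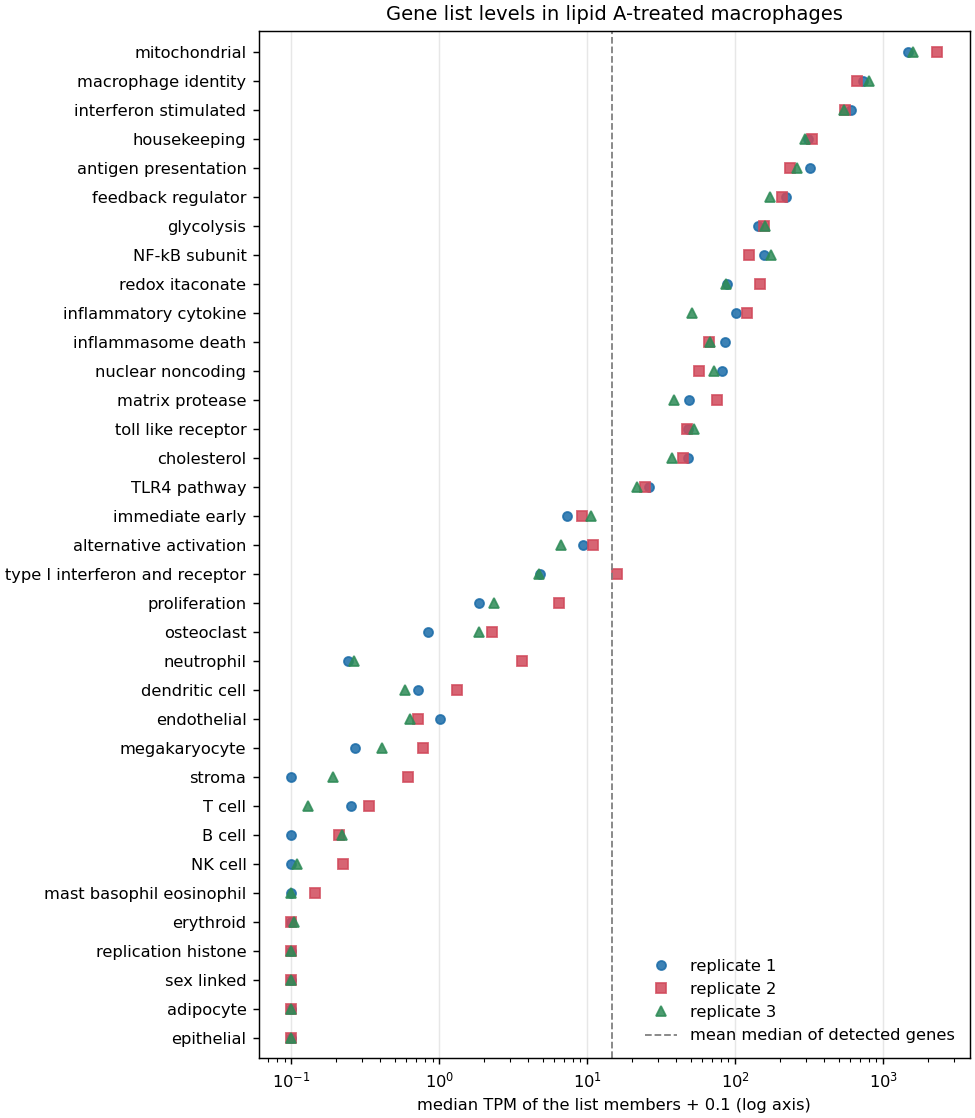
Median TPM plus 0.1 of each gene list (horizontal log axis) in replicates 1, 2 and 3, with the lists ordered by mean; the dashed line is the mean over replicates of the median detected gene, 14.6 TPM, plus 0.1. Macrophage identity and interferon-stimulated lists lie near 736 and 569 TPM in all 3 replicates, and the lists of other cell types lie to the left of the line.

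Antigen presentation genes stood at a level of 4.20 ± 0.25 with 15 of 15 detected; B2m, H2-D1 and H2-K1 led, and Ciita, the regulator of class II genes, was lowest at 5.08 ± 1.10 TPM. Cd40 exceeded the costimulatory gene Cd86 by 3.38 ± 0.45 (log2), and Cd80 lay below Cd86 with a ratio of -1.58 ± 0.35. Markers of alternative activation had a level of -1.08 ± 0.26 with 6 of 10 detected: Mrc1, the mannose receptor gene, stood at 227 ± 47.1 TPM, Ccl22 at 39.4 ± 22.3 TPM and Clec10a at 35.0 ± 10.2 TPM, while Retnla had 0 counts. Immediate-early genes had a level of -0.72 ± 0.30 with 11 of 15 detected. Junb reached 252 ± 67.3 TPM and exceeded Jun by 2.56 ± 0.13, and Fosl1 had 0 counts. Both lists changed side when only detected members were kept, to 0.74 and 0.013.

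Glycolysis genes were all detected (17 of 17) at a level of 3.37 ± 0.10, with Gapdh at 1110 ± 207 TPM and Pfkl lowest at 11.1 ± 1.68 TPM. The hexokinase gene Hk2 exceeded Hk1 by 0.90 ± 0.38, but by 0.13 in the second quantification. The itaconate and redox list stood at 2.77 ± 0.37 with 11 of 12 detected. Acod1, which encodes the enzyme that makes itaconate, led with 1850 ± 286 TPM, ahead of Prdx1 and Sod2 at 1127 ± 274 and 832 ± 113 TPM; Nqo1 was lowest at 1.15 ± 0.201 TPM. Cholesterol genes had a level of 1.52 ± 0.18 (12 of 12 detected), led by the efflux transporter gene Abca1 at 88.5 ± 28.3 TPM, which exceeded Abcg1 by 0.57 ± 0.45; Hmgcs1 stood at 59.8 ± 19.3 TPM. Inflammasome and cell death genes had a level of 2.30 ± 0.22 (13 of 13 detected), with Casp4 at 262 ± 84.4 TPM, Casp1 at 238 ± 73.4 TPM and Gsdmd at 168 ± 52.3 TPM. Matrix protease genes had a level of 1.69 ± 0.42 with 9 of 10 detected, led by Mmp13 at 820 ± 221 TPM. Proliferation genes had a low level, -2.28 ± 0.92, with 10 of 18 detected; Pcna, the replication clamp gene, led at 277 ± 74.0 TPM, followed by Mki67 at 27.2 ± 1.17 TPM and Mcm6 at 21.4 ± 5.40 TPM. Housekeeping genes lay at 4.41 ± 0.02 (11 of 11), nuclear noncoding RNAs at 2.22 ± 0.28 (6 of 6) and genes of the mitochondrial chromosome at 6.90 ± 0.31 (15 of 15). Replication-dependent histone genes, whose transcripts lack a poly(A) tail, had 0 of 12 members detected and a level of -7.20 ± 0.05. That level is the floor of the scale, given by a median of 0 TPM in every replicate.

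Markers of other cell types were low as lists, between -7.20 ± 0.05 for epithelial and adipocyte markers and -4.01 ± 0.53 for osteoclast markers. The epithelial and adipocyte medians were 0 TPM in every replicate, so -7.20 is the floor set by the added 0.1 TPM. Its SD is the spread of the median detected gene and not of the markers. The T cell, B cell, natural killer cell, mast cell and erythroid medians averaged 0.14 TPM or less, so these levels lie near that floor. T cell, B cell and natural killer cell lists stood at -6.05 ± 0.65, -6.47 ± 0.64 and -6.77 ± 0.60, and mast cell, basophil and eosinophil markers at -7.05 ± 0.22. Erythroid, stromal and endothelial lists stood at -7.18 ± 0.09, -6.02 ± 1.29 and -4.33 ± 0.22. Dendritic cell and megakaryocyte lists had levels of -4.19 ± 0.56 and -5.15 ± 0.69. The neutrophil list, at -4.68 ± 2.02, varied most between replicates, with 4 of 12 members detected; it was -3.99, -5.80 and -4.07 without replicates 1, 2 and 3. The stromal level was -5.38 without replicate 1 and -6.67 without replicate 2. With only detected members kept, the T cell, neutrophil, megakaryocyte and adipocyte levels became 2.00, 1.62, 1.40 and 3.72. Single members of these lists were nevertheless abundant: Cd4 at 62.8 ± 10.4 TPM and Cd28 at 61.6 ± 13.5 TPM, where 3 of 10 T cell markers were detected, Fabp4 at 138, 543 and 97.6 TPM in replicates 1, 2 and 3 with 1 of 5 adipocyte markers, and Pf4 at 322, 1001 and 226 TPM with 2 of 6 megakaryocyte markers. The sex-linked list stood at the floor of -7.20 ± 0.05 with 1 of 6 members detected, and at 1.62 from that member alone: the X-chromosome transcript Xist was seen in every replicate (52.2, 68.2 and 26.1 TPM), whereas the Y-chromosome genes Ddx3y and Eif2s3y had 0 counts in all 3.

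Over the 30 pairs, 28 had all replicates on the same side, 29 had a mean larger than its SD and 21 differed by more than 2-fold. Every list level and each of these 28 pairs gave p = 0.25 in the exact sign-flip test, the smallest p that 3 replicates allow. Further pairs were Il12b/Il10 at 2.81 ± 0.44 (log2), Cxcl2/Cxcl1 at 0.85 ± 0.29, Ccl4/Ccl3 at 0.74 ± 0.41 and Fcgr1/Fcgr3, genes of antibody receptors, at -1.66 ± 0.24. Counts without length scaling moved further ratios by more than 1.5-fold without a change of side: Cxcl10/Cxcl9 to 4.48, Ccl5/Ccl2 to 1.45, Il6/Tnf to -4.21, Il12b/Il10 to 3.43, Il12b/Il12a to 7.58, Il12b/Il23a to 8.58 and Ptgs2/Ptgs1 to 3.82. The same scale moved Nfkbia/Nfkbie to 1.47, Cd40/Cd86 to 2.52, Il1rn/Il1b to 0.65, Ifit3/Ifit1 to -1.21, Junb/Jun to 1.63, Abca1/Abcg1 to 1.47 and Fcgr1/Fcgr3 to -0.66. Il12b/Il23a was also 6.63 in the second quantification and 6.71 with a pseudocount of 1 TPM.

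**Figure D2:**
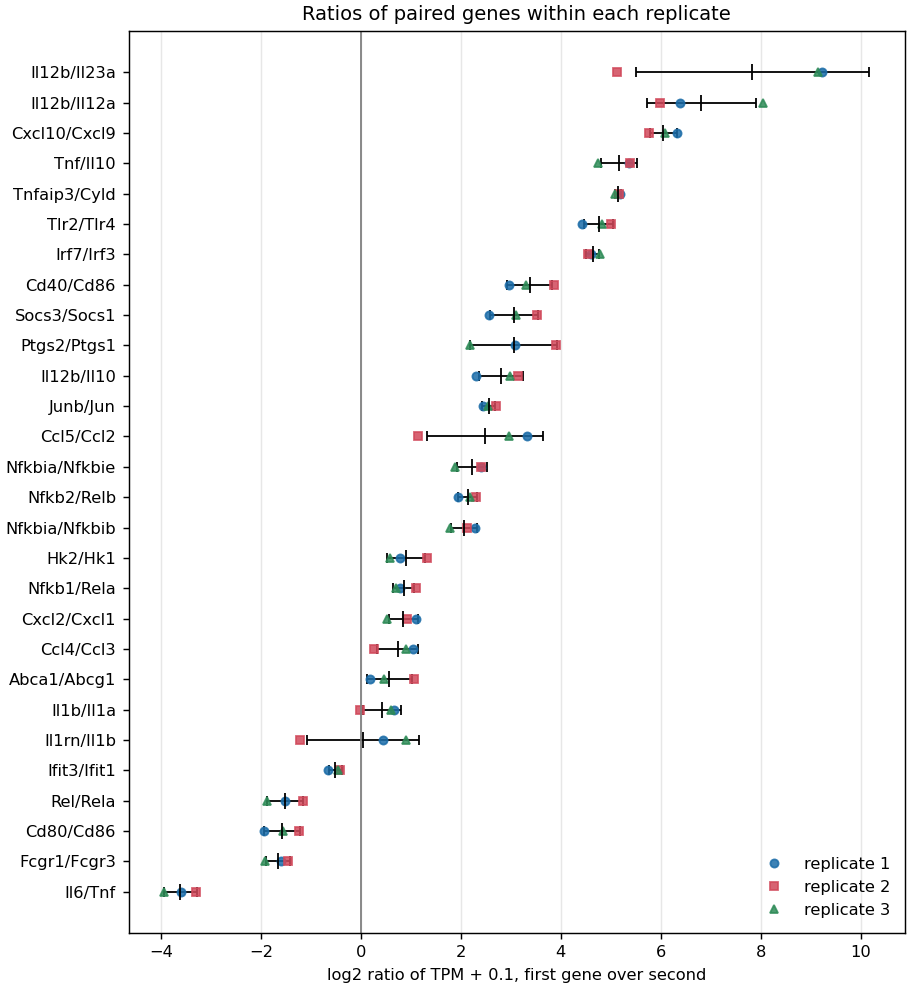
Log2 ratio of TPM plus 0.1 (horizontal axis) for 28 of the 30 gene pairs; symbols are replicates 1, 2 and 3, the vertical tick is their mean and the bar its SD (n = 3). Tnfaip3/Cyld lies at 5.14 ± 0.06, whereas Il1rn/Il1b spans 0 at 0.04 ± 1.12.

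Replicates differed from each other by more than counting noise. The common biological coefficient of variation was 23.1% (edgeR), and 8999 of 11611 genes (77.5%) departed from equal rates in the chi-square test with Benjamini-Hochberg adjustment. For replicates 1 and 3 alone the coefficient was 0.194, against 0.247 for replicates 2 and 3 and 0.248 for replicates 1 and 2. Each pair of libraries differed beyond counting noise in 50.6% of genes or more, so no library had been deposited more than once. Across detected genes, which are not independent replicates, Pearson's r of log2 TPM between libraries lay between 0.972 and 0.979.

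Cytokine genes were higher in replicate 2 and lower in replicate 3, while interferon-stimulated genes deviated less. Rsad2 stood at 6294, 6264 and 5199 TPM in replicates 1, 2 and 3, and Ifit3 at 1671, 1643 and 1600 TPM. Oas2 and Mx2, members of the list chosen after their values were seen, varied more, with 133, 81.5 and 57.8 TPM and 435, 311 and 225 TPM. Il1a (chromosome 2, 129299610 to 129309972) had 415, 2418 and 357 TPM, Il1b 661, 2399 and 544 TPM, and the monocyte chemokine gene Ccl2 764, 2817 and 707 TPM. Cxcl3 had 3.04, 37.2 and 1.55 TPM. Tnf differed less, with 1637, 1843 and 1086 TPM, and Ccl4 had 5234, 5159 and 2892 TPM. Of 23 tested inflammatory genes, 20 were highest in replicate 2, and the median deviation of the list was 0.82 (log2) from the other replicates, at the 100th percentile of matched random lists, whose central 95% ran from -0.22 to 0.15. In replicate 3 the list deviated further, by -1.08 (0th percentile), with 21 of 23 genes lowest there. Against replicate 1 alone the list was higher by 0.50 and against replicate 3 alone by 1.34. The interferon-stimulated list deviated by 0.22 in replicate 1 (99.2nd percentile; 29 of 32 genes higher) and by -0.17 in replicate 3 (0.15th), where it was -0.04 and inside the range of random lists without replicate 1. In replicate 2 it deviated by -0.12, inside that range, and by -0.28 against replicate 1 alone, outside it. All 23 inflammatory and all 32 interferon-stimulated genes passed the chi-square test, adjusted over the list alone and over all genes, which does not set them apart, since 77.5% of all tested genes did. The median gene-wise coefficient of variation was 0.283 in the first list, at the 100th percentile of matched random lists, and 0.187 in the second, at the 63.7th.

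**Figure D3:**
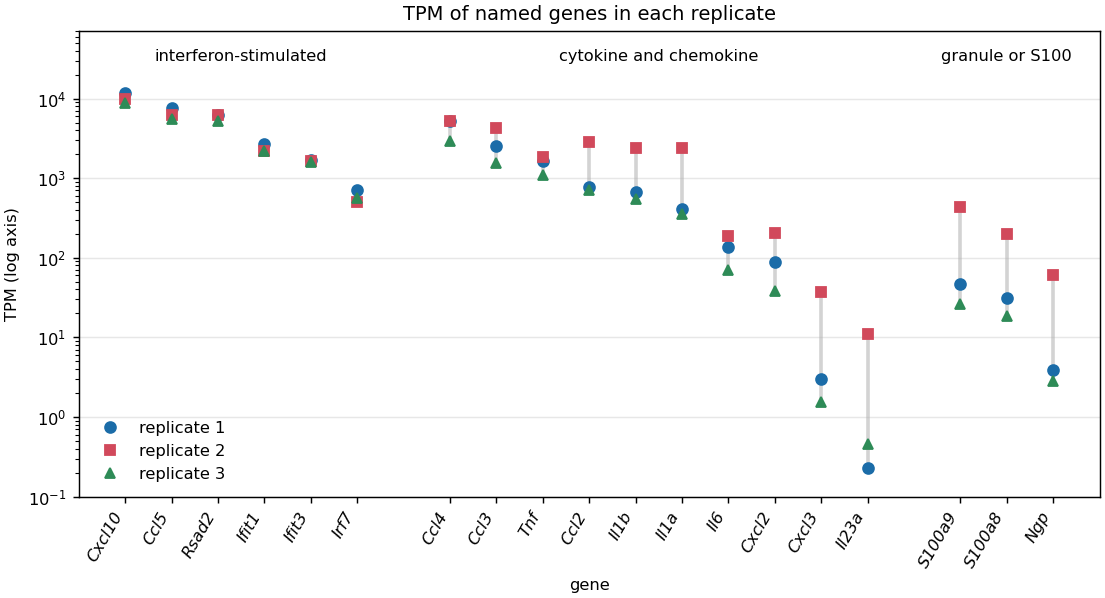
TPM (vertical log axis) of named interferon-stimulated, cytokine and chemokine, and granule or S100 genes in replicates 1, 2 and 3; grey lines join the lowest and highest replicate. Il1a spans 357 to 2418 TPM, and Cxcl10 spans 8809 to 11864 TPM.

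Other lists also stood apart in replicate 2. Proliferation genes were higher by 1.53 (log2) in the median, with 14 of 15 tested members highest in that replicate, although Mki67 had 28.5, 26.3 and 26.9 TPM. Neutrophil markers were higher by 3.43 (10.8-fold) in the median of the 5 members tested out of 12, with 4 highest in that replicate. S100a9, a calcium-binding protein gene (chromosome 3, 90692632 to 90695721), had 47.1, 432 and 26 TPM, S100a8 31.0, 196 and 18.7 TPM, and the granule protein gene Ngp 3.94, 60.6 and 2.85 TPM. Matrix protease genes were higher by 0.66 in the median, megakaryocyte markers by 1.93 (3 members tested) and dendritic cell markers by 0.70 (7 members tested). Osteoclast markers (3 members tested) were higher by 0.82, but by 0.26 against replicate 3 alone, inside the range of random lists. Genes of the mitochondrial chromosome were higher by 0.50, and by 0.11 after trends on gene length and GC content were removed, a step chosen after seeing the data. Lists that were lower in replicate 2 were cholesterol (-0.52), endothelial (-0.49, 4 members tested), antigen presentation (-0.43), immediate-early (-0.27) and macrophage identity genes (-0.26). Of these, antigen presentation stayed outside the range of random lists in every alternative run. Removal of the same trends moved immediate-early and macrophage identity genes inside it, to -0.11 and -0.05, and deposited TPM gave -0.04 for macrophage identity. Against replicate 1 alone, immediate-early (-0.07), macrophage identity (-0.16) and endothelial genes (-0.52) lay inside the range, and against replicate 3 alone cholesterol genes did (-0.23). Among single genes with a mean of 10 TPM or more, Cd36, a scavenger receptor gene, was among the 10 with the largest spread, with 66.8, 752 and 162 TPM.

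Without replicate 2, inflammatory genes were still higher in replicate 1 than in replicate 3, by 0.62 in the median (100th percentile), and interferon-stimulated genes by 0.26 (at the 99.97th). Proliferation genes were lower by 0.47 in replicate 1 than in replicate 3, and neutrophil markers were higher by 0.73. Over 26 lists and 3 replicates, 35 of 78 medians lay outside the central 95% of random lists: 8 lists were higher and 5 lower in replicate 2, 4 higher and 6 lower in replicate 1, and 2 higher and 10 lower in replicate 3. Without replicate 2, 8 lists were higher and 2 lower in replicate 1; without replicate 3, 3 were lower in replicate 2; without replicate 1, 4 were higher in replicate 3. These ranks describe the libraries and have no p-value, since each sets a single library against the others.

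**Figure D4:**
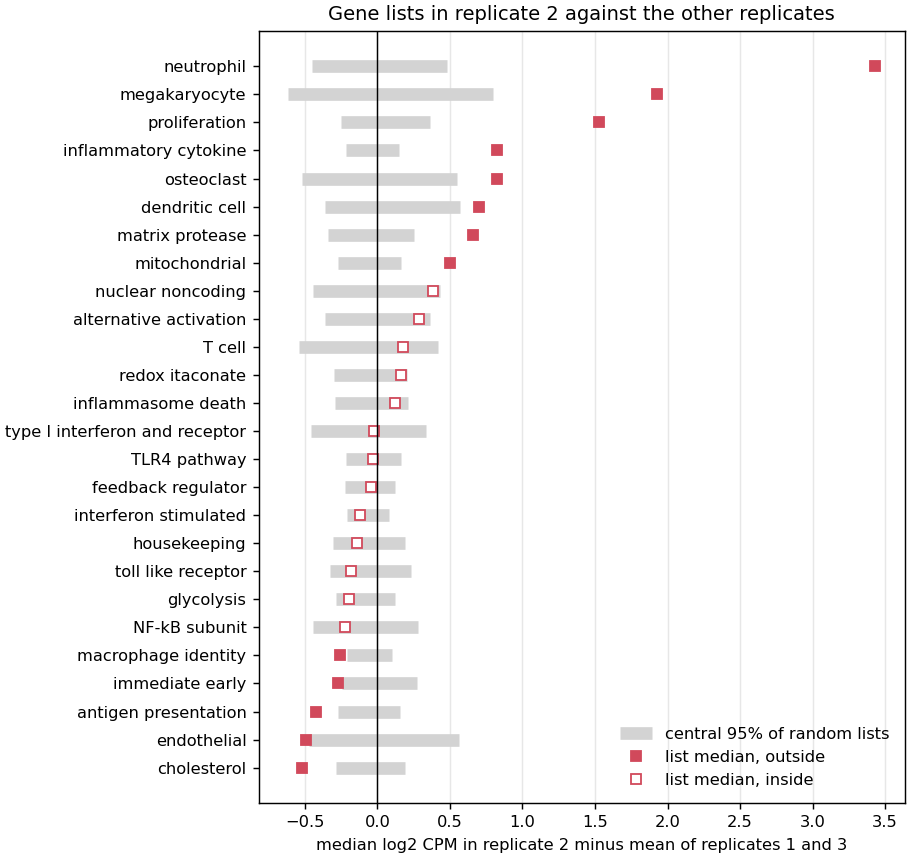
Median difference in log2 CPM of each of 26 gene lists between replicate 2 and the mean of replicates 1 and 3 (horizontal axis, squares), with the central 95% of 10000 expression-matched random lists (grey bars); filled squares lie outside it. Neutrophil markers (5 members tested) lie at 3.43, proliferation genes at 1.53 and inflammatory genes at 0.82.

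Few genes made up a large part of the RNA. The 10 most abundant genes of each library held 18.7 ± 3.16% of summed TPM (SD, n = 3; 29.2% in the second quantification), the 50 most abundant 36.5 ± 1.64% and the 100 most abundant 44.9 ± 1.39%. Nuclear protein-coding genes held 83.7 ± 2.72% and genes of the mitochondrial chromosome 6.17 ± 1.74%. The mitochondrial share leaves out nuclear copies identical to mt-Co2, mt-Co3 and mt-Atp6, found by sequence search (closing section). In replicates 1, 2 and 3, Gm28661 held 9418, 14366 and 7511 TPM, Gm28437 5847.5, 10140 and 6453.5 TPM, and Gm10925 7289, 9238 and 5483 TPM. Reads of these genes and their copies were not told apart, so the share may be understated. CT010467.1, a gene annotated as ribosomal RNA and chosen after its values were seen, held 2%, 1.80% and 8.22% of TPM in replicates 1, 2 and 3. The short mitochondrial gene mt-Atp8 stood at 30048 ± 11043 TPM in the main quantification, with 0.231 times that level in the second, and mt-Co1 stood at 10339 ± 2015 TPM.

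By estimated shares of TPM, most named genes were assigned mainly to a single transcript. Of 108 named genes with more than 1 annotated transcript and 1 TPM or more, 100 had the same leading transcript in both quantifications. In 52 of the 108 the leading transcript made up more than 90% of the gene in the main quantification. Tnf-201 held 99.9 ± 0.0% of Tnf (SD, n = 3), Cxcl10-201 97.1 ± 1.2% of Cxcl10 and Nos2-201 100.0 ± 0.0% of Nos2. The leading transcript was not protein-coding in some genes: Tnip3-205, a retained-intron transcript, held 62.4 ± 3.7% of Tnip3, Apoe-202, a processed transcript, 63.1 ± 6.7% of Apoe, and Mmp12-204, annotated for nonsense-mediated decay, 58.0 ± 4.5% of Mmp12. The retained-intron transcript Sod2-204 led Sod2 at 37.5 ± 4.9%, and transcripts not annotated as protein-coding together held 85.3% of that gene. Such shares are estimates that divide reads among overlapping transcripts and scale them by length. Tnip3, Apoe, Mmp12 and Sod2 kept their leading transcripts in the second quantification. A kept leader did not fix the share: Ctsd-202 held 77.8% of Ctsd in the main and 98.1% in the second. Whether most RNA of such genes is non-coding was not tested. Leading transcripts differed between quantifications for genes such as Relb, where Relb-202 held 86.5 ± 1.8% in the main and 27.1 ± 4.8% in the second. At the gene level, 129 of 141 named genes with a mean of 1 TPM or more agreed within 1.5-fold between the quantifications, and 6 differed by more than 2-fold.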

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

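Sequences outside the mouse annotation exceeded the 3 counts that a count of 0 allows, phiX in every replicate and ERCC in replicate 1 of the second quantification only; no control library was there to compare them with. The phiX sequence, a common control in sequencing runs, had 28650 expected counts in replicate 1, 34450 in replicate 2 and 49716 in replicate 3, which is 0.117%, 0.0993% and 0.082% of each library's counts. The second quantification assigned 11 counts to ERCC spike-in sequences in replicate 1, against 2 and 3 in replicates 2 and 3, which do not exceed it, while the main quantification assigned 0 in every replicate. No explanation was tested for either signal, and both were left out of the library sizes used for the spread between replicates. The scale of deposited TPM includes phiX, at 348, 290 and 246 TPM.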

How the results depend on the processing

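Leaving out replicates from the list deviations and the Nos2/Arg1 count ratio, and removing length and GC trends from the deviations, were chosen after seeing the data; all other alternatives were planned. Detected genes, genes beyond counting noise and shared leading transcripts stayed within 1.5 times under each alternative run. Of 240 alternative list levels, 232 kept their sign. The other 8 arose when only detected members were kept, which drops the low members: type I interferon and receptor 2.67, alternative activation 0.74, immediate-early 0.013, T cell 2.00, neutrophil 1.62, megakaryocyte 1.40, adipocyte 3.72 and sex-linked 1.62. Of 180 alternative pair ratios, 176 kept their sign. Without length scaling, Il1b/Il1a became -0.24 and Rel/Rela 0.21. Over left-out replicates, Il1rn/Il1b ranged from -0.40 to 0.67. Of the alternative list deviations, 480 stayed inside or outside the random range as before, some of those inside it with a change of sign, 36 moved inside it, 27 moved outside it and 3 that lay outside it reversed. In the second quantification, 58 of 165 named genes moved by more than the SD between replicates. The 10 most abundant nuclear protein-coding genes were all lower in it, at 0.615 to 0.919 times the main level. Such moves can therefore include a shift shared between genes. The coefficient of variation was 0.269 with no filter on low counts and ranged from 0.194 to 0.248 over left-out replicates, lowest without replicate 2. In the second quantification the 10, 50 and 100 most abundant genes held 29.2%, 45.3% and 52.6% of TPM; nuclear protein-coding genes alone gave 31.4% for the 50 and 39.8% for the 100; the cause was not tested. With each replicate set against a single other, the number of lists higher in replicate 1 ranged from 3 to 8 and lower from 2 to 9, lower in replicate 2 from 3 to 4, and higher in replicate 3 from 2 to 4. The deviation of proliferation genes in replicate 3 ranged from -1.17 to 0.47, of neutrophil markers in replicate 1 from -2.96 to 0.73, and of megakaryocyte markers in replicate 1 from -1.86 to 0.089, since replicate 2 was left out at the upper end. No paired analysis was possible because the labels give 1 group. Depth limits genes near 0: 3 counts are 1.23e-05% of the shallowest library.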

Other observations

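Tests of the scaling factor, length and GC trends, the neutrophil markers, RNA without a poly(A) tail and nuclear copies were chosen after the patterns were seen; of these, only the test of length and GC trends had its limits set before its own outcome was known.

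Several genes listed as markers of other cell types were expressed here without most of the companion markers of their lists. Among T cell markers, of which 3 of 10 were detected, Cd4 and Cd28 had 50.9 to 70.0 and 49.8 to 76.4 TPM over the 3 replicates. Cd3e, chosen after its values were seen, had 0, 0.18 and 0 TPM. Among endothelial markers, 2 of 6 were detected, and the list median was 0.905, 0.62 and 0.535 TPM in replicates 1, 2 and 3. Kdr had 17.0, 7.52 and 18.8 TPM and Vwf 15.7, 6.20 and 18.2 TPM, with Tek, also chosen after its values were seen, at 0 TPM. Transcripts not annotated as protein-coding held 51.9% of Vwf in the main quantification, and its leading transcript differed between the quantifications. Fabp4, a fatty acid binding protein gene, had 138, 543 and 97.6 TPM against 0 counts of Adipoq, and Pf4, a platelet chemokine gene, had 322, 1001 and 226 TPM against 2.04, 10.1 and 2.05 TPM of Ppbp and 0.1, 0.36 and 0.17 TPM of Gp9, the last again chosen afterwards.

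Neutrophil granule and proliferation genes were higher in replicate 2, and cytokine genes were higher in replicate 2 and, by a larger deviation of -1.08 (log2), lower in replicate 3; the tests here cover replicate 2 only. A single scaling factor of the library would shift all lists by the same log2 amount. The inflammatory and interferon-stimulated lists moved apart by 0.94 (log2) in replicate 2, which such a factor alone cannot do. The upper limit for the central 95% of random differences was 0.26, but both list deviations were known when this comparison was chosen. Trends on gene length and GC content took 18.4% of the variance of the deviations; after their removal the inflammatory list still deviated by 0.59, from 0.82 before, above the upper limit of 0.063 for random lists, which argues against these trends as the whole cause. Of 10 neutrophil markers with at least 10 expected counts, 9 (90%) were highest in replicate 2, Csf3r being the exception and Ly6g having 0 counts (both chosen after their values were seen), but these markers make up the pattern itself, so granule genes from neutrophil-lineage cells and from the macrophages cannot be told apart. The stromal marker Dcn had 0, 5.12 and 0.02 TPM in replicates 1, 2 and 3, and Pdgfrb 0.34, 0.54 and 0.50 TPM. In contrast, the endothelial markers Kdr and Vwf were lowest in replicate 2. Whether cells of other types contributed was not tested. As the labels give 1 group, no biological explanation of a difference between cultures was tested, and it stays open.

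The annotated ribosomal RNA gene CT010467.1 (chromosome 17, 39846353 to 39848827), chosen after its values were seen, had 20041, 18006 and 82217 TPM in replicates 1, 2 and 3. Less complete removal of RNA without a poly(A) tail in replicate 3 may contribute in part: the small RNA genes of that kind with a mean of 1 TPM or more had a median deviation of 0.46 (log2) in replicate 3, at the 99.4th percentile of matched random lists, which is far less than the 4.57-fold range of CT010467.1. This rests on 4 genes, counting identical copies once, of which 3 were higher, among them Rn7sk with 65.8, 59.1 and 88.7 TPM. Replication-dependent histone genes, which also lack that tail, had a list median of 0 TPM in every replicate. Hist1h2ae had 0.80, 0.63 and 0.91 TPM in replicates 1, 2 and 3, and Hist1h4d 0.07, 0.20 and 0.06 TPM. Values this near the floor cannot decide the question. The nuclear noncoding list, which also holds Rn7sk, was lower in replicate 3 by a median of -0.70, with Neat1 at 96.1, 125 and 28.4 TPM. Against replicate 2 alone this list deviated by -0.21 and against replicate 1 alone by -0.36, both inside the range of random lists. Ribosomal RNA content of the samples was not measured and stays open, and no biological explanation was tested.

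The mitochondrial genes mt-Co2, mt-Co3 and mt-Atp6 differed by 26.8-fold, 14-fold and 43.7-fold between their highest and lowest replicate in CPM. Each has 1 nuclear copy on chromosome 1 that is 100% identical over 681, 783 and 678 nt: Gm28661 (24614885 to 24615565), Gm28437 (24613189 to 24613971) and Gm10925 (24613974 to 24614651). Summed with its copy, each of the 3 genes varied less, by 1.94-fold, 1.61-fold and 1.76-fold. The copies held at least 87.3% of each sum and by themselves varied by 1.94-fold, 1.67-fold and 1.71-fold, so the sums had to vary less, and reads shared with the copies cannot be told apart from other causes. Within the identical stretches, the sequence of a read does not tell a gene from its copy. The fold ranges of the genes alone can therefore not be read as differences in their expression between replicates. In the second quantification, the mean TPM of mt-Co2, mt-Co3 and mt-Atp6 was 1.76, 6.67 and 22.5 times that in the main quantification. The levels of these genes therefore depend on the quantification. No biological explanation was tested.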
